A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

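Messenger RNA was measured by sequencing in 12 libraries of Saccharomyces cerevisiae in the BY4741 background. The labels describe 10 groups. Wild type (WT) and mmm1Δ in YPD, a rich glucose medium, have 2 libraries each, and every other group has 1. Cultures in YPD were taken at an OD600 of 0.8 to 1, per the labels' protocols. WT was also grown in a medium the labels call clean YPD, alone or with 100 µM bathophenanthroline disulfonate (BPS), an iron chelator, for 4 hours. Libraries were made with a TruSeq or a KAPA stranded kit, per the labels' protocols, which do not say which library had which kit.

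The authors deposited FPKM values (fragments per kilobase, scaled to the mapped fragments) for 6660 genes in 3 tables, per the file headers. TopHat2 2.0.8, Cuffdiff 2.0.2 and the genome build sacCer3 are named per the labels' processing notes, which give neither their roles nor their settings. The first table holds WT replicate 1, mmm1Δ replicate 1 and mdm34Δ. The second holds WT replicate 2, mmm1Δ replicate 2, VPS13-D716H, VPS13-D716H mmm1Δ, sam37Δ, VPS13-D716H sam37Δ and AFT1-C291F. The third holds WT in clean YPD with and without BPS. No library is in more than 1 table. Median FPKM was 12.3 to 15.5 in the first table, 40.2 to 44.3 in the second and 50.4 to 52.2 in the third, and 273 genes have another length in the first table, so the tables were taken as normalized separately. Cuffdiff can also scale values within a table, which the notes do not state.

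Depth is unknown. Low FPKM values were checked for steps of 1 read: per library, 10.0 to 28.0% of 50 low values lay within 0.05 of a whole multiple of the smallest, too few to recover reads, so no count test was run and no counting error is given. Genes listed at 0 numbered 98 to 243 per library. In all 12 libraries the ratio of a dubious gene to the gene antisense to it had a median of 0.41 to 0.55 over 185 pairs. The genes of each pair were listed at the same locus, and the partner had a mean FPKM above 50. For such pairs strand was thus in effect not used, and overlapping and antisense genes are uncertain. Of the 6660 genes, 5986 matched the reference annotation of assembly R64 by identifier and 5365 had a locus with the same ends as the reference gene. A shared locus was listed for 1304 genes, and 434 were shorter than 300 nt. Coordinates are those of the annotation.

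Ratios are log2 of (FPKM + 1) in 1 library over another of the same table. This scale understates the change of low genes. Genes with a mean FPKM of at least 5 over the libraries compared were used, and a 2-fold ratio was counted as higher or lower. Comparisons of single libraries have no p and no replicate check. For mmm1Δ, 2 pairs share no library, and genes past 2-fold in the same direction in both were counted beside n1 × n2 / N, the count for independent lists. The planned limma fit without a block was to be run only if the tables were normalized alike. They were not, so neither it nor a fit over all 12 libraries was run. For that case the plan was to give only values per pair, with no p. The calls and adjusted p in the text depart from that plan. They come from limma with the replicate number as a block, an alternative written with it, which compares mmm1Δ with WT within each table. Settings were limma 3.58.1 in R 4.3.3, trend on, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. For the 4 libraries the replicate number is the table, per the labels, and deviations of WT and mmm1Δ with the same number had a correlation of 0.62 across 6029 genes, which were taken as paired. The fit has 1 residual degree of freedom and 7.59 prior degrees of freedom. Each SE given is the moderated SE of this fit. It draws on the spread over all genes and is not the spread of the 2 pairs. The words rose and fell are kept for calls of this fit.

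Gene lists were written from general knowledge of yeast before the data were examined. They cover the Aft1/Aft2 iron regulon, Yap5 targets, iron-sulfur and heme enzymes, the respiratory chain with ATP synthase, the tricarboxylic acid cycle, retrograde targets, the mitochondrial ribosome, mitochondrial import, the endoplasmic reticulum (ER) to mitochondria contact, Pdr1/Pdr3 drug resistance, heat shock, the proteasome, the unfolded protein response, Msn2/Msn4 stress, Yap1, cytosolic ribosomal proteins, ribosome biogenesis, ergosterol, phospholipids, hypoxic and cell wall mannoprotein genes, zinc, copper, phosphate, biotin, Gcn4, Met4, glycolysis, glucose-repressed genes, MATa, MATα and meiotic genes, mitochondrially encoded genes and strain markers. The ribosomal protein list was set by a name pattern and takes in RPP1 of nuclear RNase P. Per comparison, the median ratio of a list was set against 10000 random lists of the same size, matched on mean expression in 20 bins and drawn outside the list. A list is said to stand apart below the percentile 2.5 or above 97.5, which describes these libraries and does not test the conditions. The mitochondrially encoded genes are in none of the tables.

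Genes are named by a rule fixed before the data were examined: the targeted gene, the 8 highest and 8 lowest ratios, any iron regulon member, and up to 3 members of each list that stands apart. Most of the extremes by this rule are open reading frames under 300 nt listed at 0 in 1 library. After that was seen, the 8 highest and 8 lowest among 5044 genes of at least 300 nt that are alone at their locus were added to the rule, and counts over these genes are given beside the counts over all genes. Other genes chosen after their values were seen are said to be so. The PAU genes, HXT6 with HXT7, and CUP1-1 have near-identical copies whose reads may be shared between them.

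The alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 20, libraries scaled by the median ratio, unmatched random lists, another control, and each replicate left out. Added after the data were seen were the genes of at least 300 nt alone at their locus, removal of a lowess trend with abundance and length (fraction 0.3), clean YPD as control for sam37Δ and AFT1-C291F libraries, and the WT library of another table as control for ribosome biogenesis in mmm1Δ replicate 1 and for HXT and stress genes in VPS13-D716H, AFT1-C291F and sam37Δ. The blocked limma fit was tested on simulated data with the mmm1Δ libraries' spread over 6029 genes. Of 150 genes planted at each change, it recovered 14.0% at a log2 of 1, 98.0% at 2, 99.3% at 3 and 100% at 4. It called 78 of 17487 unchanged genes, or 0.4%, beside 21, 147, 149 and 150 true calls at those changes. False calls were thus a larger share of all simulated calls than the adjusted p threshold allows. The mmm1Δ calls may therefore hold more false ones than that threshold states. The list test was run on simulated lists of 20 genes in VPS13-D716H sam37Δ over sam37Δ. It set apart 7 of 200 lists with no shift and 200 of 200 with a shift of 0.25. That comparison has the smallest SD of ratios over genes, 0.51 against 1.33 in mdm34Δ, so a small shift may be missed elsewhere. The simulated lists were drawn at random, so the rate with no shift need not hold for co-regulated genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.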

Results

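The data describe how mutants of contacts between mitochondria and other organelles, an iron chelator and an activated iron regulator affect gene expression in budding yeast. Of the 12 libraries, WT and mmm1Δ in YPD have 2 each. The groups mdm34Δ, sam37Δ, VPS13-D716H, VPS13-D716H mmm1Δ, VPS13-D716H sam37Δ, AFT1-C291F, WT in clean YPD and WT in clean YPD with BPS have 1 library each and so no replicates. Genes for cytosolic ribosomal proteins held between 27.0 and 54.9% of the length-weighted FPKM of a library. Values from different tables differ by more than genotype: WT replicate 2 over WT replicate 1 had a median log2 ratio of 1.52, with 3818 genes higher and 392 lower. Ratios are therefore taken within a table unless stated.

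Deleted genes checked the labels. MMM1 (YLL006W, chromosome XII, 136586 to 137866 in build sacCer3) was listed at 0 in mmm1Δ replicate 1, mmm1Δ replicate 2 and VPS13-D716H mmm1Δ. In the other libraries its FPKM was 6.48 in WT replicate 1, 6.03 in mdm34Δ, 37.6 in WT replicate 2, 36.0 in VPS13-D716H, 28.3 in sam37Δ, 20.8 in VPS13-D716H sam37Δ, 35.6 in AFT1-C291F, 48.2 in clean YPD and 36.8 with BPS. MDM34 (YGL219C, chromosome VII, 82878 to 84257) was listed at 0 in mdm34Δ, and was 9.38 and 15.9 in WT and mmm1Δ of the same table and between 34.3 and 72.6 in the others. SAM37 (YMR060C, chromosome XIII, 391532 to 392515) was listed at 0 in sam37Δ and in VPS13-D716H sam37Δ, and was 6.28 to 11.8 in the first table, 30.4 to 57.9 in the other libraries of the second, and 21.4 and 22.0 in the third. The point alleles in VPS13 (YLL040C, chromosome XII, 54211 to 63645) and AFT1 (YGL071W, chromosome VII, 372012 to 374084) cannot be read from expression. VPS13 FPKM was 1.16 to 1.85 in the first table, 4.92 in WT replicate 2, 5.32 in VPS13-D716H, 5.09 in mmm1Δ replicate 2, 9.34 in VPS13-D716H mmm1Δ, 4.07 in sam37Δ, 4.05 in VPS13-D716H sam37Δ and 13.7 in AFT1-C291F, and 6.56 and 6.31 without and with BPS. AFT1 was at 56.2 in the AFT1-C291F library and 10.03 in WT of its table. The strain markers LEU2, URA3 and MET17, deleted in BY4741, lay between 0 and 1.69 in all libraries, and HIS3, of which this background keeps a part, between 53.8 and 331.

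Mmm1 sits in the ER membrane and is a subunit of ERMES, a complex that tethers the ER to mitochondria and moves lipids between them. Mitochondria make iron-sulfur clusters, and the supply of clusters tells the activators Aft1 and Aft2 whether the cell has enough iron. When clusters are short, Aft1 turns on the iron regulon, the genes for iron uptake at the surface, release of vacuolar iron and sparing of iron. The comparison of mmm1Δ with WT asks, from the title of the series, whether loss of the contact alters iron control. The 2 pairs came from separate tables.

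At 2-fold, 232 genes were higher and 224 lower in mmm1Δ in both pairs, where independent lists would share 43.0 and 54.4. These counts are over the 6029 genes that passed the filter over the 4 libraries. There 504 and 514 genes were higher in pairs 1 and 2, and 806 and 407 lower. With a trend with abundance and length removed, 196 of the 232 and 94 of the 224 were kept, and lower genes were 126. Among genes of at least 300 nt alone at their locus the counts were 174 and 146. Filtered on its own libraries, pair 1 alone had 417 genes higher and 794 lower of 5038, and pair 2 had 533 and 416 of 6222. Across 4986 genes the ratios of the pairs had a Pearson correlation of 0.48 and a Spearman correlation of 0.47, over genes, which are not independent replicates. In the blocked limma fit of 6029 genes 165 rose and 61 fell, and 1143 had an unadjusted p under 0.05. Calls depended on the filter: with none 20 rose and 3 fell, and 14 of 51 called genes named in the text were still called, while longer genes alone at their locus gave 364 and 179.

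The iron regulon had the highest median of all lists, 1.83 over both pairs. Of its 29 measured members 17 rose over all genes tested and 25 when adjusted over the list alone, and none fell by either count. The cell wall mannoproteins FIT1, FIT2 and FIT3 hold iron-siderophore complexes at the cell surface. FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) went from FPKM 142 to 17547 in pair 1 and from 52.5 to 18121 in pair 2. Its mean log2 ratio was 7.67 ± 0.53 (moderated SE, limma adjusted p 0.000116). FIT2 (YOR382W, chromosome XV, 1059531 to 1059992) rose by 6.24 ± 0.63 (SE; limma adjusted p 0.000794), and FIT1 (YDR534C, chromosome IV, 1503314 to 1504900) by 6.11 ± 0.32 (SE; limma adjusted p 2.77e-05). The siderophore transporters ARN1, ARN2, SIT1 and ENB1 rose by 4.45, 5.51, 4.66 and 3.40. LSO1 (YJR005C-A, chromosome X, 448477 to 448758), a small gene whose product associates with ribosomes, rose by 8.32 ± 0.52 (SE; limma adjusted p 6.4e-05). TIS11, whose product degrades transcripts of iron-using proteins, rose by 4.20 ± 0.38 (SE; limma adjusted p 0.000426). The reductases FRE1, FRE3 and FRE5 rose by 1.78, 2.10 and 1.47. The vacuolar iron exporter genes FTH1 and FET5 rose by 2.15 and 1.88, the biotin transporter VHT1 by 2.38, COT1 by 1.83 and ECM4 by 2.04.

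FET3 (YMR058W, chromosome XIII, 388822 to 390732), the oxidase of the high-affinity system, was higher in both pairs at 1.26 and 2.33, with a limma adjusted p of 0.0659. Its partner permease FTR1 was at 0.59 and 2.31 (limma adjusted p 0.192), and the copper supply gene CCC2 had a mean of 1.43 (limma adjusted p 0.0502). FRE6, SMF3, MRS4 and ISU1 were higher in both pairs as well, and like FET3, FTR1 and CCC2 passed only when adjusted over the list. ATX1 was lower by 0.38 in pair 1 and higher by 2.33 in pair 2. HMX1, a heme oxygenase gene, had a mean of 0.27 and FRE4 of -0.19.

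**Figure D1:**
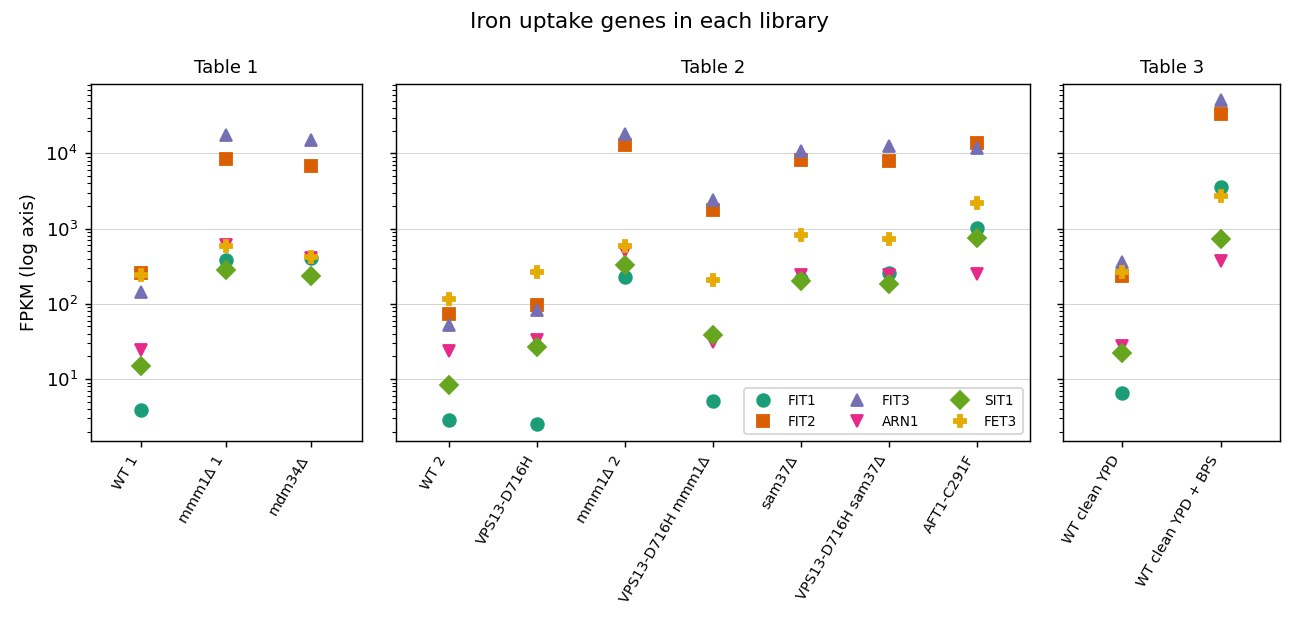
FPKM on a log axis of FIT1, FIT2, FIT3, ARN1, SIT1 and FET3 in each library, 1 panel per table. FIT3 was at 142, 52.5 and 356 in the WT libraries without BPS and at 10669 or more in mmm1Δ, mdm34Δ, sam37Δ, VPS13-D716H sam37Δ, AFT1-C291F and with BPS; it was at 2405 in VPS13-D716H mmm1Δ.

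Genes of iron-sulfur and heme enzymes were lower, with a median of -1.16. Of 23 members, 5 fell over all genes tested and 14 adjusted over the list alone. The cytochrome c gene CYC1 fell, at -2.45 and -2.56 in the pairs (moderated SE 0.38, limma adjusted p 0.0084). The flavohemoglobin YHB1 fell by 2.10, the biotin synthase BIO2 by 1.75, the Rieske protein RIP1 by 1.68 and SDH2 of succinate dehydrogenase by 1.496. ILV3, the iron-sulfur dehydratase of branched-chain amino acids, was at -1.96 and passed only when adjusted over the list. In the respiratory chain and ATP synthase 11 of 35 fell, or 19 adjusted over the list alone, with a median of -1.30. They include COX5A, COX4 and QCR10 at -2.24, -2.19 and -2.19, QCR2 at -2.13 and SDH1 at -1.78. COX26, listed at 0 in mmm1Δ replicate 1 and at 51.0 in replicate 2 against 529 in WT replicate 2, fell as well. Against this, the tricarboxylic acid list had IDH1 up by 2.13 with SDH1 and SDH2 down, 1 higher and 2 lower of 15, or 2 and 4 adjusted over the list alone. IDH1 is also a retrograde target, one of the genes that Rtg1 and Rtg3 turn on when mitochondria fail. CIT2, the peroxisomal citrate synthase and usual reporter of that pathway, rose by 2.25 ± 0.35 (SE; limma adjusted p 0.00957), and the 7 retrograde targets had 2 rises and no fall, or 3 rises adjusted over the list alone.

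Some drug resistance and anaerobic cell wall genes rose too. The Pdr1/Pdr3 list had a median of 1.36, with 6 of 15 members up over all genes and 9 adjusted over the list alone. YLR346C rose by 4.94, the lipid exporter gene RSB1 by 2.81 and the drug pump gene PDR5 by 2.62. In the hypoxic and cell wall mannoprotein list 8 of 15 rose, or 10 adjusted over the list alone, with DAN1 up by 7.69 ± 0.36 (SE; limma adjusted p 2.77e-05), TIR4 by 5.60 and the sterol importer AUS1 by 3.54. PAU5, of a family of near-identical genes, rose by 6.69, and PAU8, listed at 0 in WT replicate 2, rose too. Among stress genes, HSP12 rose by 5.12 and YGP1 by 2.93, while the Msn2/Msn4 list had a median of 0.30 and 2 rises of 18, or 2 rises and 1 fall adjusted over the list alone.

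Other lists had few calls. The Met4 list had none of 22 over all genes and 3 falls adjusted over the list alone, Gcn4 targets had 2 rises of 25 or 4 rises and 3 falls, and ergosterol genes had none of 24 or 4 falls. MATa genes had 2 falls of 7 or 3, with AGA2 at -2.32 and ASG7 at -1.87. Biotin genes had 2 rises and 1 fall of 5 by both counts, and phosphate genes 1 of each of 14 by both, with PHO5 at -2.34. Heat shock genes had 1 rise of 19 or 2, Yap1 targets 1 rise of 13 or 2 rises and 3 falls, and glucose-repressed genes 2 rises of 13 by both counts. The Yap5 list had no call of 4 or 1 fall, zinc no call of 9 or 1 rise, copper no call of 6 or 2 rises, and MATα and meiotic genes, with 3 and 5 members, no call or 1 rise each. The ER to mitochondria contact list had 1 call of 9 by both counts, the deleted MMM1.

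Several lists had no call in the limma fit by either count: mitochondrial import (23 members), proteasome (32), unfolded protein response (14), ribosome biogenesis (26), phospholipids (13), glycolysis (16), the mitochondrial ribosome (66) and cytosolic ribosomal proteins (138). Of the mitochondrial ribosome genes 52 of 66 were above 0 in both pairs, led by MRPS17 at 1.21 and MRPS5 at 1.13. Of the ribosomal protein list, whose name pattern also takes in RPP1 of nuclear RNase P, 136 of 138 were below 0 in both, with a median of -1.66 in pair 1 and -1.03 in pair 2, or -0.10 and -0.69 once a trend fitted on other genes was removed. In the import list PAM16 was highest at 0.75. Against random lists, the medians over both pairs that stood apart beyond those given were 1.00 for retrograde targets, 0.51 for the mitochondrial ribosome, 0.17 for import, -0.25 for Met4, -0.28 for glucose-repressed genes, -1.35 for ribosomal proteins and -1.71 for MATa. The dihydroorotate dehydrogenase URA1 fell by 2.22 and YLR042C fell by 2.49. By the fixed rule the extremes also hold YOR335W-A, YDL247W-A and YEL008C-A, listed at 0 in both WT libraries, and YKL156C-A, YDR169C-A, YBR103C-A, YNL067W-A, YML007C-A and YPR108W-A, listed at 0 in mmm1Δ replicate 2. These are short and 3 of them share a locus.

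**Figure D2:**
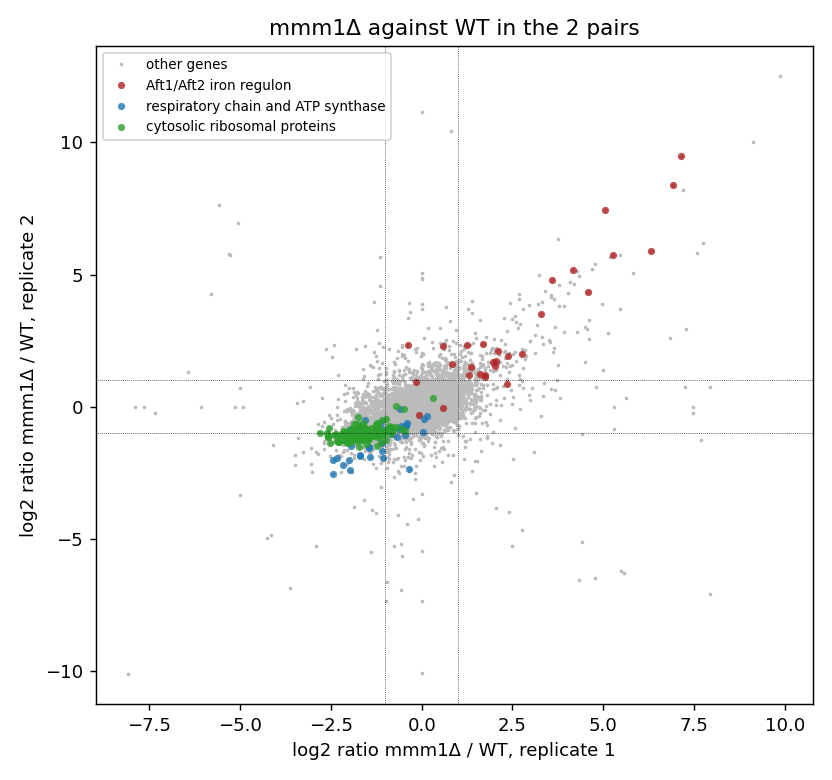
The log2 ratio of each gene in mmm1Δ over WT in pair 2 against pair 1, with iron regulon, respiratory and ribosomal protein genes in colour. The iron regulon lies high in both pairs with medians of 2.05 and 1.95, and ribosomal protein genes lie lower in pair 1 than in pair 2.

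Mdm34 is another subunit of ERMES, on the mitochondrial side of the tether. Without either subunit the complex does not form, so the comparison asks whether a second way of losing the contact gives the same profile. The mdm34Δ library has WT replicate 1 as its control.

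In mdm34Δ 604 genes were higher and 1204 lower of 5136, with 585 lower after trend removal and 553 lower against WT replicate 2, or 434 and 754 of genes of at least 300 nt alone at their locus. The iron regulon had a median of 2.07, with 21 of 27 members at least 2-fold higher and none lower. LSO1 was at 946 against 3.53, FIT3 at 14911 against 142 and FIT1 at 411 against 3.86. FIT2, ARN1, ARN2, SIT1 and TIS11 were higher by 4.74, 3.99, 5.42, 3.93 and 3.74. FET3 was higher by 0.77 only and FTR1 was at -0.12. The hypoxic list had a median of 1.86, with DAN1 higher by 7.01, TIR4 by 5.37 and AUS1 by 3.64. PAU5 was at 417 against 0.898. Drug resistance genes had a median of 1.34, led by YLR346C at 4.00, RTA1 at 2.70 and PDR5 at 2.37. CIT2 was higher by 2.23 and IDH1 by 1.56 among retrograde targets, whose median was 0.80. HSP12 and the vitamin B6 gene SNZ1 were higher by 5.66 and 5.52.

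Respiratory genes were lower with a median of -1.64, including CYC1 at -3.70, QCR10 at -3.004 and COX5A at -2.97. Iron-sulfur and heme enzymes had a median of -1.15, with the peroxidase CCP1 at -3.52 and ILV3 at -3.20. BAT1, of branched-chain amino acid synthesis, was at -2.80. The phosphatidylinositol synthase PIS1 was at -2.53 in a phospholipid list with a median of -1.25, and CWP1, a cell wall protein, was at -3.47. MATa genes had a median of -2.89 with AGA2 at -3.65. The mitochondrial ribosome and ribosome biogenesis lists were higher at 0.41 and 0.85, and the proteasome list at 0.37, led by RPT1, which shares its locus, at 1.16. The import list was at -0.15 and the Gcn4 list at -0.06, both above their random lists. Both turned positive, at 0.54 and 0.59, once a trend with abundance and length was removed. With WT replicate 2 as control and centred ratios, the proteasome and ribosome biogenesis medians were -0.40 and -0.058. Ribosomal protein genes had a median of -2.11 with RPL23B at -3.24 and RPS31 at -3.22, and glycolysis genes -2.07, but neither list stood apart from genes of similar abundance. YOR335W-A, YDL247W-A and other short frames listed at 0 in WT lead the fixed rule.

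Set against each other within their table, mdm34Δ and mmm1Δ replicate 1 differed little. Only 37 genes were higher and 109 lower in mdm34Δ, or 2 and 18 of the longer genes alone at their locus, and the iron regulon median was -0.17. Across tables, mdm34Δ over WT replicate 1 and mmm1Δ over WT replicate 2, which share no library, had a Pearson correlation of 0.45 and a Spearman correlation of 0.41 over 5095 genes. They shared 203 higher genes where independent lists would share 51.7, and 252 lower where these would share 85.5.

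BPS binds ferrous iron outside the cell and starves it of iron, so the response gives a measure of the iron regulon under true iron limitation. Cells then give up respiration and other iron-costly steps while they take up more iron. Both libraries were WT in clean YPD, in the same table.

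With BPS 199 genes were higher and 245 lower of 6262, or 100 and 146 of longer genes alone at their locus, and 496 and 765 against WT replicate 2 with ratios centred. The iron regulon had a median of 2.23, and 28 of 30 members were at least 2-fold higher, FRE4 and FRE5 falling short at 0.97 and 0.93. FIT3 went from 356 to 51534, FIT2 from 236 to 33041 and FIT1 from 6.47 to 3600. LSO1 was listed at 0 without BPS and was at 2846 with it. SIT1, TIS11 and FRE2 were higher by 4.98, 4.81 and 5.03. FET3 and FTR1 were higher by 3.34 and 3.13, and HMX1, which frees iron from heme, by 4.33. PBI1 and the oxidoreductase OYE3 were higher by 4.05 and 3.66. In the zinc list ZRT1 was higher by 2.42 and the low-affinity metal transporter FET4 by 1.96, and ERG3, an iron enzyme of ergosterol synthesis, was higher by 1.51. IDH1 was higher by 1.16 among retrograde targets, whose median was 0.63.

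Iron-sulfur and heme enzymes were lower with a median of -1.99, 17 of 23 by at least 2-fold. LEU1 and GLT1, iron-sulfur enzymes of leucine and glutamate synthesis, were at -3.87 and -3.09, CYC1 at -3.49, CCP1 at -3.02 and ILV3 at -2.63. The flavoprotein CIR2 was at -3.22 and YER156C at -3.66. Respiratory genes had a median of -1.17, with SDH2, SDH3 and SDH1 at -2.88, -2.52 and -2.32. The tricarboxylic acid list was at -0.75. Among Yap5 targets, which respond to high iron, the glutaredoxin GRX4 was at -2.10 and the vacuolar iron importer CCC1 at -2.06. Catalase CTT1 was at -2.36 in a stress list with a median of -0.82. BAT1 was at -1.42, MET5, a heme and iron-sulfur enzyme, at -1.82, and AGA2 at -1.61.

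Other lists stood apart from genes of like abundance with small medians. These were 0.38 for hypoxic genes, led by TIR1 at 2.12, 0.38 for zinc, 0.34 for ergosterol, 0.23 for the unfolded protein response and 0.22 for Yap1. Lower medians were -0.54 for MATa, -0.30 for the mitochondrial ribosome, -0.29 for heat shock, -0.27 for phosphate, -0.25 for glycolysis, -0.21 for Met4 and -0.13 for Gcn4. Ribosomal protein genes were at 0.03. Against WT replicate 2 instead, with ratios centred, the Yap1, zinc, ergosterol and ribosomal protein medians turned to -0.20, -0.28, -0.063 and -1.65, and over longer genes alone at their locus the retrograde median was -0.14. Drug resistance genes had a median of -0.09 and did not stand apart, unlike in mmm1Δ and mdm34Δ.

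BPS and mmm1Δ were compared over pairs that share no library. With pair 1 the Pearson correlation over 4951 genes was 0.25 and the Spearman correlation 0.15, and 84 higher and 82 lower genes were shared where independent lists give 13.5 and 30.8. With pair 2 these were 0.27 and 0.13 over 6112 genes, with 108 and 81 genes against 14.9 and 15.0. Without the iron regulon the Pearson correlations were 0.18 and 0.19.

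**Figure D3:**
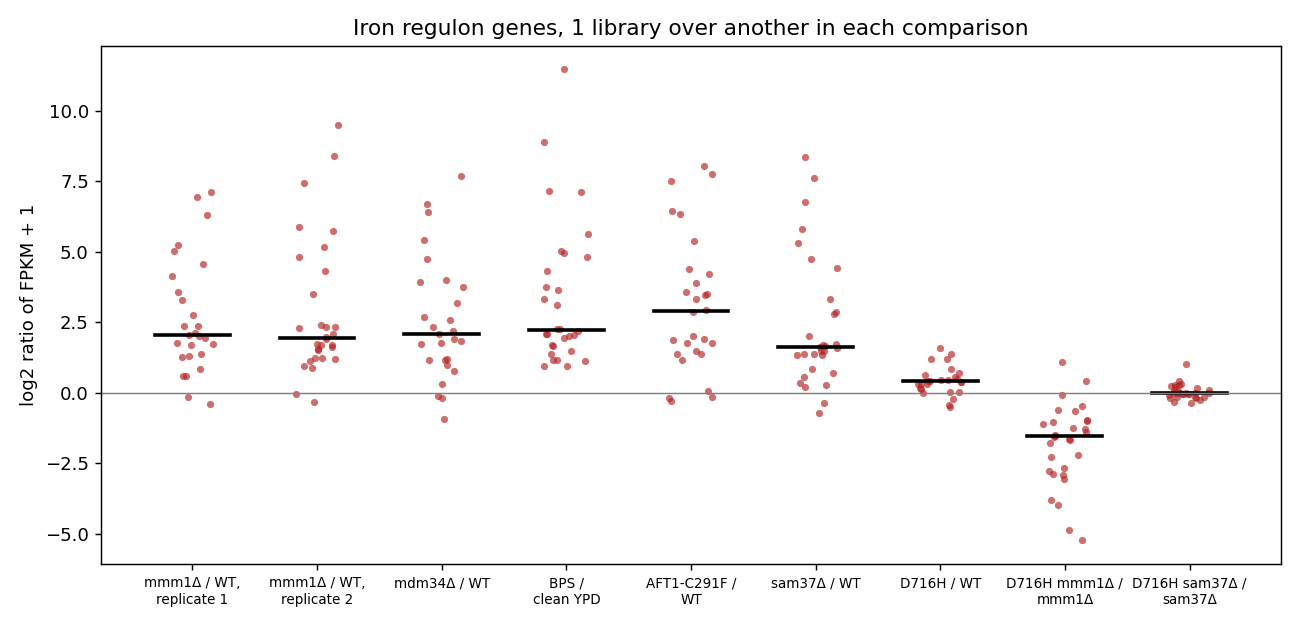
The log2 ratio of each measured iron regulon member (points) and the median (bar) in each comparison. Medians are 2.07 in mdm34Δ, 2.23 with BPS, 2.91 in AFT1-C291F, 0.41 in VPS13-D716H, -1.55 for VPS13-D716H in mmm1Δ, 1.61 in sam37Δ and -0.02 for VPS13-D716H in sam37Δ.

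Aft1 is held out of the nucleus, or off DNA, when iron-sulfur clusters are plentiful. The exchanged cysteine in AFT1-C291F lies in the part that senses this, so the allele keeps the iron regulon on in iron-rich medium. The comparison asks which genes follow Aft1 activity when contacts and iron supply are intact. WT replicate 2 is its control. The AFT1 transcript was also higher in this library than in that control. Effects of the exchange and of a higher AFT1 level therefore cannot be told apart.

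In AFT1-C291F 965 genes were higher and 878 lower of 6174, or 695 and 496 of longer genes alone at their locus, and 456 and 539 after trend removal. The iron regulon median was 2.91, and 24 of 28 members were at least 2-fold higher. Against WT replicate 1, with ratios centred, that median was 1.65 and 1869 genes were lower. FIT1 was at 1026 against 2.85, FIT3 at 11634 against 52.5, FIT2 at 13822 against 74.1 and SIT1 at 754 against 8.35. FET3 and FTR1 were higher by 4.21 and 3.50, more than in mmm1Δ, and FRE2 and TIS11 by 4.40 and 5.39. MRS4, ISU1, ISU2 and ECM4 stayed between -0.29 and 0.06. LSO1, high in mmm1Δ and with BPS, was at 2.91 against 1.47, under the filter.

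Beyond iron, SRO9, which encodes an RNA-binding protein, was higher by 4.15, and ribosome biogenesis genes had a median of 0.72 with UTP20, RRP5 and UTP10 higher by 2.41, 2.38 and 2.17. The unfolded protein response list was at 0.52, with KAR2 and LHS1 higher by 1.26 and 1.44. HAC1, which shares its locus, was at 1189 against 318. The chaperones HSP30 and SSA2 were higher by 1.54 and 1.502, and the phosphate transporter PHO84 by 1.41 in a list with a median of 0.34, or -0.21 against WT replicate 1. Respiratory genes had a median of -1.76, 32 of 35 at least 2-fold lower, with SDH2, SDH1, CYC1 and SDH3 at -3.76, -3.15, -3.12 and -2.96. BIO2 was at -2.999 among iron-sulfur and heme enzymes, whose median was -0.96. The tricarboxylic acid and mitochondrial ribosome lists were at -0.71 and -0.77, MRPL28 at -1.69. Stress genes had a median of -1.24, with DDR2 at -4.63, and HXK1 and GPH1, both at shared loci, at -5.32 and -3.98. MATa genes had a median of -1.60. HXT7, near-identical to HXT6, was at 83.4 against 958, and CYC7 was at -3.72. Ratios of some of these genes may rest on WT replicate 2: against WT replicate 1 and centred, DDR2, HXK1, GPH1 and HXT7 were at -2.43, -3.98, -0.48 and -0.86. The stress list did not shrink in that way and was at -1.72. WT replicate 1 is in another table, so the choice of control and the table cannot be told apart. Ribosomal protein genes were at -0.73 and glycolysis genes at -0.12, but clean YPD as control turned these to 0.88 and 0.49. Trend removal turned them to 0.32 and 0.47. The respiratory list was itself at -1.04 in clean YPD over WT replicate 2. With clean YPD or WT replicate 1 as control and centred ratios, its median in AFT1-C291F stayed negative. How far the size of that median rests on WT replicate 2 is open.

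AFT1-C291F over WT replicate 2 and mmm1Δ over WT in pair 1 had a Pearson correlation of 0.18 and a Spearman correlation of 0.25 over 4931 genes. The Pearson correlation was 0.295 over longer genes alone at their locus, 0.0995 after trend removal and 0.1085 with a pseudocount of 0.1. They shared 89 higher genes against 43.7 for independent lists and 236 lower against 125. The genes higher in pair 1 had a median of only 0.0134 in AFT1-C291F, within their random lists, and 74 of them were at least 2-fold lower there. With BPS, a pair chosen after the data were seen, AFT1-C291F had correlations of 0.12 and 0.10, the Pearson correlation being 0.044 without the iron regulon, and shared 64 higher and 104 lower genes against 27.0 and 32.1.

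Vps13 carries lipids at contacts of mitochondria with the vacuole and with other membranes. The D716H exchange is of a kind that lets cells without ERMES grow better. The library with the allele alone shows what it does when ERMES is present, and WT replicate 2 is its control.

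With VPS13-D716H alone 136 genes were higher and 129 lower of 6160, but only 44 and 38 of longer genes alone at their locus, and 674 and 1621 against WT replicate 1 with ratios centred. Iron regulon genes had a median of 0.41. The 4 members past 2-fold were SIT1 at 1.57, FRE1 at 1.36, FTR1 at 1.20 and FET3 at 1.18, while FIT1 was at 2.49 against 2.85. YRO2, TDA6, TPO2 and HSP30 were higher by 2.90, 2.49, 2.36 and 2.004, and YLR162W by 4.45. Named lower genes include HXT7 at -3.06, HXT6 at -2.96, GSY1 at -2.70, PGM2 at -2.32, EMI2 at -2.25 and GLC3 at -1.92, with HXK1 and GPH1, at shared loci, at -2.78 and -3.10. STR3 and CYC7 were at -2.37 and -1.90. List medians that stood apart were -0.63 for stress, -0.33 for Met4, -0.32 for glucose-repressed genes, -0.31 for the tricarboxylic acid cycle, -0.30 for respiration, -0.21 for ribosomal proteins, 0.28 for drug resistance and 0.35 for heat shock. Some of these may rest on WT replicate 2: HXT7 was at 958 there, 7569 in VPS13-D716H mmm1Δ and 83.4 to 259 in the rest of that table. With WT replicate 1 as control and centred ratios the medians were -0.73 for iron, -0.37 for stress, 0.10 for respiration and -0.54 for drug resistance. HXT7 was then at -0.39. That control is in another table, so the choice of control and the table cannot be told apart.

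The double mutant asks whether the allele undoes the response to loss of ERMES, and its control is mmm1Δ replicate 2. Since both libraries lack Mmm1, their ratio shows the allele in cells without ERMES.

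In VPS13-D716H mmm1Δ over mmm1Δ 589 genes were higher and 751 lower of 6245, or 363 and 557 of longer genes alone at their locus. The iron regulon median was -1.55, with 22 of 30 members at least 2-fold lower and 1, HMX1, higher by 1.11. FIT1 was at 5.07 against 228 in mmm1Δ, ARN1 at 30.7 against 499, LSO1 at 60.2 against 1787 and SIT1 at 39.0 against 333. FIT2 and FIT3 were lower by 2.90 and 2.91 but still at 1760 and 2405, against 74.1 and 52.5 in WT. Over WT the iron regulon had a median of 0.71 and 9 of 27 members were at least 2-fold higher.

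The anaerobic cell wall genes were lower, with DAN1 at -5.09, TIR4 at -4.71 and AUS1 at -3.82, and PAU5 at -5.21. PAU8 was at 41.6 in mmm1Δ and listed at 0 in the double mutant. Drug resistance genes had a median of -0.91, with PDR5 at -3.17 and YLR346C at -2.70. CIT2 and IDH1 were at -1.601 and -2.09 in a retrograde list with a median of -1.38. PBI1 and HES1 were at -4.52 and -4.41. Respiratory genes had a median of 2.30, 33 of 36 at least 2-fold higher, with QCR10, SDH1, QCR6 and RIP1 higher by 3.83, 3.70, 3.58 and 3.29. Iron-sulfur and heme enzymes and the tricarboxylic acid list were higher at 1.27 and 1.501. Over WT too the respiratory list was higher, at 0.85, and the tricarboxylic acid list at 1.06.

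Further changes concern sugar, stress and growth. HXT7 and HXT6 were higher by 4.86 and 4.79, SPG4 by 5.01, RGI2 by 4.63, HXT4 by 3.59 and the invertase SUC2 by 2.62, while HXT1, the carrier used at high glucose, was at 31.3 against 736. The stress list had a median of 1.76, 15 of 18 at least 2-fold higher, with DDR2 and CTT1 higher by 3.07 and 3.02. The Met4 list was at 1.76 too, with MET6, MMP1 and MUP1 higher by 3.05, 2.96 and 2.61. CWP1 was higher by 3.82. Ribosome biogenesis genes had a median of -1.69, 23 of 26 at least 2-fold lower, UTP10 at -2.47 and NSR1, at a shared locus, at -2.85. Medians of 1.04 for glucose-repressed genes, 0.93 for MATa, 0.89 for Yap5 targets, 0.49 for phospholipids, -1.12 for hypoxic genes, -0.26 for Gcn4 and -0.13 for the mitochondrial ribosome also stood apart. Ribosomal proteins stood apart at 0.12 and at -0.20 after trend removal. Over WT, stress and glucose-repressed genes were at 2.28 and 1.43 and ribosome biogenesis at -1.93.

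Genes at least 2-fold higher in mmm1Δ pair 1, libraries that do not enter this ratio, were followed in the double mutant. Of 417, 410 were measured, with a median of -0.75 over mmm1Δ replicate 2 where random lists gave -0.05 to 0.10, and 174 were at least 2-fold lower against 33 higher. Without the iron regulon the median was -0.69. Over WT the same genes had a median of 0.42, between WT and the 1.00 of mmm1Δ pair 2. Genes lower in pair 1, 794 with 780 measured, had a median of 0.31 against 0.07 to 0.16, or 0.71 after trend removal, and 142 were at least 2-fold higher and 28 lower.

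**Figure D4:**
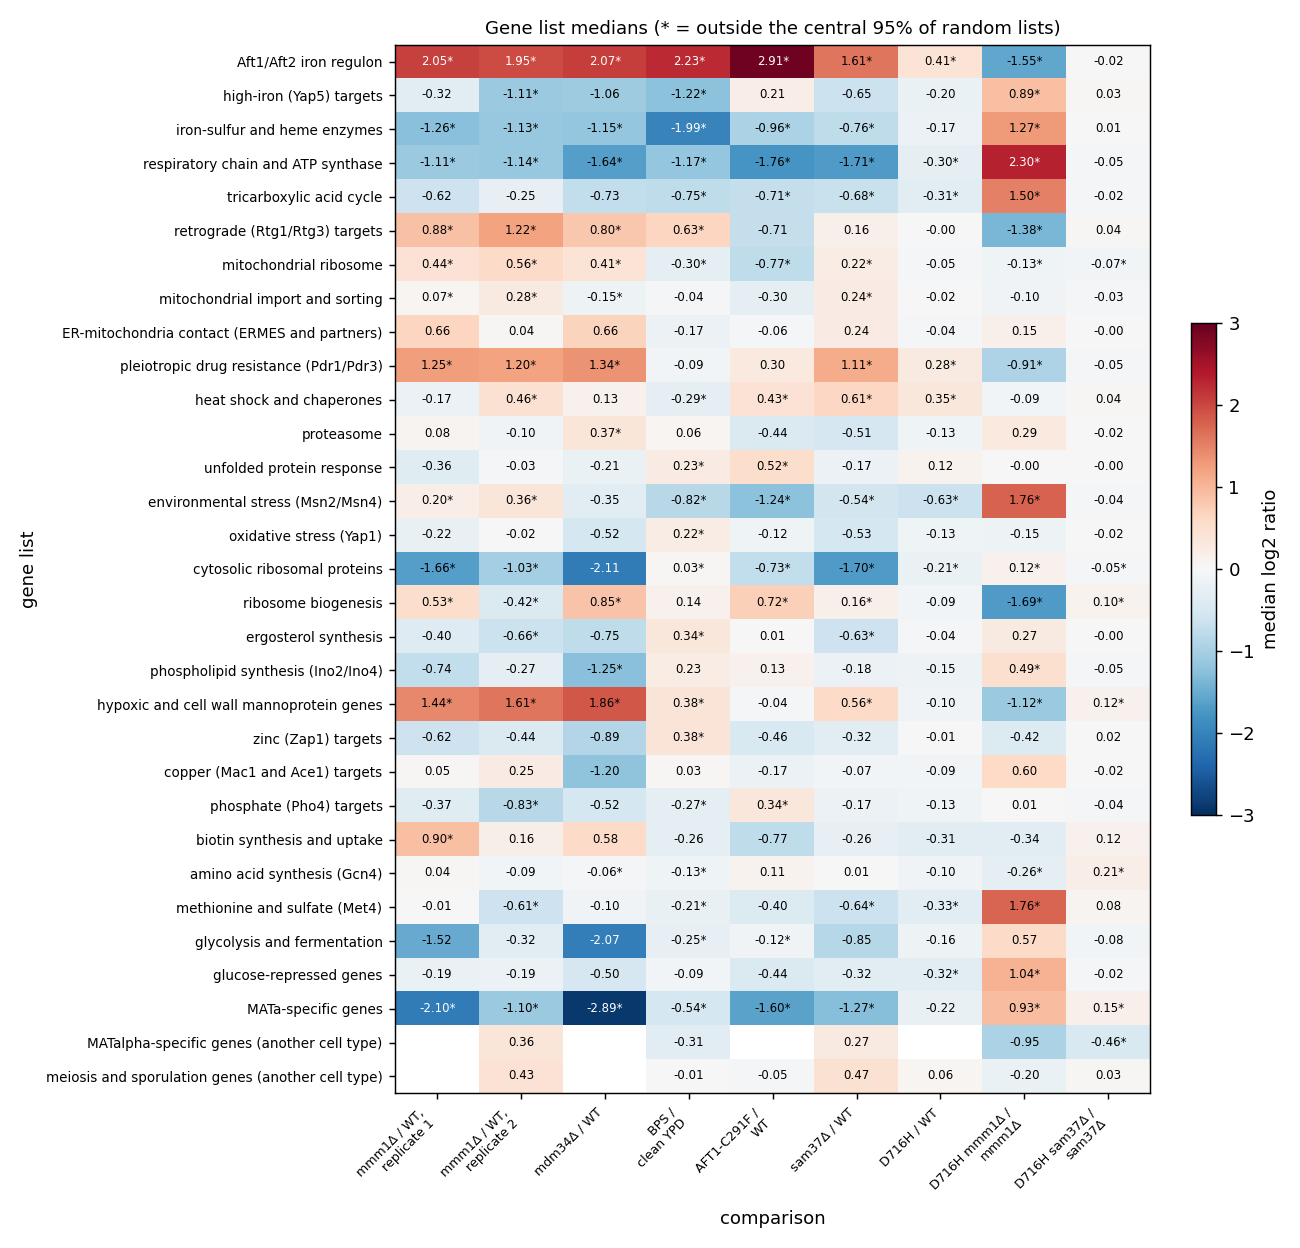
Median log2 ratio of each gene list (rows) in each comparison (columns) by colour, with a star where it lay outside the central 95% of 10000 random lists matched on expression. The iron regulon is at 2.05 and 1.95 in mmm1Δ pairs 1 and 2, 1.61 in sam37Δ and -1.55 for VPS13-D716H in mmm1Δ. Respiratory genes are at -1.11, -1.14, -1.71 and 2.30 in the same order.

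Sam37 is a subunit of the machinery that sorts barrel-shaped proteins into the mitochondrial outer membrane. ERMES itself needs a barrel protein, Mdm10, as its anchor there, so sam37Δ asks whether a defect on the mitochondrial side gives a like response. The control is WT replicate 2.

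In sam37Δ 392 genes were higher and 665 lower of 6198, or 221 and 366 of longer genes alone at their locus. With clean YPD as control and centred ratios, a choice made after the data were seen, these were 229 and 141, and with WT replicate 1 932 and 1780. Of 30 iron regulon members 22 were at least 2-fold higher, with a median of 1.61, or 0.99 against WT replicate 1. LSO1 was at 807 against 1.47, FIT3 at 10669 against 52.5, FIT2 at 8201 against 74.1 and FIT1 at 214 against 2.85. TIS11, SIT1, ARN1 and FET3 were higher by 4.74, 4.43, 3.31 and 2.78. Drug resistance genes had a median of 1.11, 11 of 17 at least 2-fold higher, with YLR346C, RSB1 and PDR5 higher by 3.78, 3.05 and 2.99. DAN1 and TIR4 were higher by 5.39 and 3.83 in a hypoxic list with a median of 0.56. Heat shock genes were at 0.61, led by HSP30 at 1.68, the import list at 0.24 (-0.78 against WT replicate 1) with PAM16 at 1.06, the mitochondrial ribosome at 0.22 and ribosome biogenesis at 0.16.

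Respiratory genes had a median of -1.71, 32 of 35 at least 2-fold lower, with QCR10 at -3.30, COX4 at -3.09, COX7 at -2.88, SDH1 at -2.57, CYC1 at -2.46 and RIP1 at -2.38. The iron-sulfur and heme, tricarboxylic acid and ergosterol lists were at -0.76, -0.68 and -0.63, ERG28 at -1.67. The Met4 list was at -0.64 with SAM2 at -2.18. HXT4, HXT7 and HXT6 were at -3.85, -3.13 and -3.02 and ALD6 at -2.74. Stress and MATa lists were at -0.54 and -1.27. With WT replicate 1 as control and centred, HXT4, HXT7 and HXT6 were at -1.603, -0.49 and -0.46, and stress, at -0.62, did not stand apart. Ribosomal protein genes had a median of -1.70, 124 of 138 at least 2-fold lower, but 0.0013 with clean YPD as control. In clean YPD over WT replicate 2 the respiratory list was itself at -1.04. With clean YPD or WT replicate 1 as control and centred ratios, its median in sam37Δ stayed negative. How far the size of that median rests on WT replicate 2 is open. Values of sam37Δ correlated at 0.93 with clean YPD, 0.93 with BPS and 0.87 with WT replicate 2, across genes. Against mmm1Δ pair 1, a pair chosen after the data were seen, sam37Δ ratios had correlations of 0.42 and 0.45, and shared 133 higher and 308 lower genes against 25.7 and 96.6.

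VPS13-D716H in sam37Δ asks whether the allele also offsets loss of Sam37. It differed little from sam37Δ: 73 genes were higher and 63 lower of 6189, and only 9 and 11 of longer genes alone at their locus, and the values of both libraries correlated at 0.97. The iron regulon median was -0.02, with FIT3 at 12484 against 10669 and ARN1 at 241 against 245. Only BNA2 of its members was past 2-fold, at 1.03. PBI1 was higher by 1.43 and PAU14 by 1.57, and COS8 and SRX1 were at -1.20 and -1.12. ARG3 and ARG1 were higher by 0.67 and 0.42 in a Gcn4 list with a median of 0.21. Small medians also stood apart: 0.15 for MATa, 0.12 for hypoxic genes, 0.10 for ribosome biogenesis, -0.05 for ribosomal proteins, -0.07 for the mitochondrial ribosome and -0.46 for 3 MATα genes, with MF(ALPHA)2 at -1.29. Trend removal took the ribosomal protein median to 0.0021. Over WT the iron regulon of this library was at 1.51 with 22 of 30 members higher, and genes higher in mmm1Δ pair 1 had a median of 0.04 over sam37Δ.

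The clean YPD library serves as the baseline for BPS. Against WT replicate 2 it is compared across tables, so medium, batch and normalization cannot be told apart. The median over all genes was 0.27. At 2-fold 782 genes were higher and 435 lower, but 375 and 665 once libraries were scaled by the median ratio. The iron regulon median was 0.65, or 0.38 centred, with FIT3 at 356 against 52.5, FIT2 at 236 against 74.1 and FRE1 at 46.1 against 14.1. YNL190W and PDR12 were higher by 2.99 and 2.54. ZRT1 was at -2.39, HXT7 at -2.35 and RPL30 at -2.39. Ribosomal protein and respiratory lists were at -1.41 and -1.04, heat shock at 0.53, Gcn4 at 0.38 and glucose-repressed genes at -0.33. The import list was at 0.22, or -0.050 when scaled. Against WT replicate 1 and centred, the iron, import and Gcn4 medians were -0.89, -1.16 and -0.61. Centred on the median of all genes, WT replicate 2 over WT replicate 1 gave -0.90 for the iron regulon and -1.50 for ribosomal proteins, a measure of how far WT libraries of different tables lie apart.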

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

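Both tests of the stress genes below were chosen after their result was seen, and the one of the allele alone replaced earlier forms that used WT only. VPS13-D716H gave medians of opposite sign in WT and in mmm1Δ for 8 lists that stood apart in both. In WT and in mmm1Δ in turn, medians were 0.41 and -1.55 for the iron regulon, -0.30 and 2.30 for respiration, -0.31 and 1.501 for the tricarboxylic acid cycle, 0.28 and -0.91 for drug resistance, -0.63 and 1.76 for stress, -0.21 and 0.12 for ribosomal proteins, -0.33 and 1.76 for Met4 targets and -0.32 and 1.04 for glucose-repressed genes. For ribosomal proteins only the sign differs: both medians lay below their random lists, which in mmm1Δ ran from 0.39 to 0.59, and the median there was -0.20 after trend removal. Each side is 1 library over 1 library, and the difference was not tested. On the WT side 3 of the 8 medians changed sign with WT replicate 1 as control and centred ratios. They were then -0.73 for the iron regulon, 0.10 for respiration and -0.54 for drug resistance, while the other 5 kept their sign. That control is in another table. Centred across the same tables, the iron regulon was at -0.90 in WT replicate 2 over 1 and -0.75 in mmm1Δ replicate 2 over 1. The sign changes therefore cannot tell the choice of control from the table.

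Stress genes were higher in VPS13-D716H mmm1Δ than in mmm1Δ, by a median of 1.76. The allele alone is argued against as the cause, since it did not raise them where Mmm1 was present: its stress median was -0.63 over WT replicate 2, -0.37 over WT replicate 1 (random lists -1.01 to 0.40) and -0.042 in sam37Δ, with 0 of 18 members at least 2-fold higher there. A culture sampled with less glucose left is a candidate explanation: HXT1 and HXT3, which are expressed at high glucose, had a mean log2 ratio of -3.13 in the double mutant over mmm1Δ, and HXT6, HXT7 and SUC2 were higher. An effect of the allele that needs loss of Mmm1 stays open, as the design holds 1 double mutant culture. Whether less glucose could also account for the lower iron regulon of that library was not tested. The same holds for its higher respiratory, tricarboxylic acid and iron-sulfur and heme lists and its lower ribosome biogenesis list. It also holds for the genes higher in mmm1Δ pair 1 that were followed there.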

How the results depend on the processing

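Chosen after results were seen were the settings with genes of at least 300 nt alone at their locus, with the trend removed and with clean YPD as control, single genes and ribosome biogenesis in mmm1Δ replicate 1 against the WT library of another table, the limma fits at a mean FPKM of at least 20 and on scaled libraries, and all settings for the correlations and for the mmm1Δ genes followed in the double mutant. Of the values that answer a comparison, 198 stayed within their spread or within 1.5 times, 79 moved past that and 2 reversed. Among single genes and other lists 2755 stayed, 400 moved without reversing, 48 were no longer called, 10 were newly called and 27 reversed. The iron regulon median stayed positive under every setting run in mmm1Δ, mdm34Δ, BPS, AFT1-C291F and sam37Δ and negative for VPS13-D716H in mmm1Δ. Where no cause is named, the cause was not tested.

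With the table as replicate block, limma called 165 genes higher and 61 lower in mmm1Δ. Calls were 248 and 124 with a pseudocount of 0.1, 20 and 3 with no filter, and 364 and 179 over genes of at least 300 nt alone at their locus. Lower calls were 26 with a pseudocount of 5 and 175 at a mean FPKM of at least 20. Of 51 called genes that the text names, 51 were still called with a pseudocount of 0.1, 44 with 5, 47 on scaled libraries and 14 with no filter. Those 14 include FIT1, FIT3, ARN1, ARN2, DAN1, TIR4 and YLR346C. Pairing by replicate number is pairing by table, so the calls rest on the block, and the unblocked fit and the fit over 12 libraries were not run because the tables were normalized separately. Without 1 replicate the blocked fit has no residual degrees of freedom, so only values are given: the mmm1Δ iron regulon median was 1.95 to 2.05 with either pair alone, against 1.83 for both.

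Genes of at least 300 nt alone at their locus gave lower counts at 2-fold, by more than their smaller number in places such as VPS13-D716H in sam37Δ, and more limma calls. Counts were 146 lower genes in mmm1Δ (224 over all genes), 754 lower in mdm34Δ (1204), 100 higher and 146 lower with BPS (199 and 245), 496 lower in AFT1-C291F (878), 44 and 38 in VPS13-D716H (136 and 129), 363 higher for VPS13-D716H in mmm1Δ (589), 221 and 366 in sam37Δ (392 and 665), 9 and 11 for VPS13-D716H in sam37Δ (73 and 63), and 499 and 195 for clean YPD (782 and 435). Iron medians were 1.96 in mmm1Δ (1.83) and 3.34 in AFT1-C291F (2.91). The correlation of AFT1-C291F with mmm1Δ pair 1 was 0.295 (0.18), and the genes higher in mmm1Δ had a median of -0.87 in the double mutant (-0.75). Reversed were Gcn4 in mdm34Δ at 0.79, retrograde targets with BPS at -0.14 and glycolysis in AFT1-C291F at 0.0131.

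With the trend with abundance and length removed, lower genes were 126 in mmm1Δ, 585 in mdm34Δ and 387 in sam37Δ. AFT1-C291F had 456 higher and 539 lower, and clean YPD 327 higher. Of the 224 lower genes of mmm1Δ 94 were kept, and of the 232 higher genes 196. Iron medians were 1.96 in mmm1Δ, 2.16 in AFT1-C291F and 0.34 in clean YPD (0.65). The correlation of AFT1-C291F with pair 1 was 0.0995, and genes lower in mmm1Δ had a median of 0.71 in the double mutant (0.31). Reversed were, in mdm34Δ, import at 0.54 and Gcn4 at 0.59, in AFT1-C291F, ribosomal proteins at 0.32 and glycolysis at 0.47, and ribosomal proteins for VPS13-D716H in mmm1Δ at -0.20 and in sam37Δ at 0.0021.

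A pseudocount of 0.1 gave an iron median of 1.92 in mmm1Δ and a correlation of AFT1-C291F with pair 1 of 0.1085. With 5, the iron medians were 1.69 in mmm1Δ and 2.48 in AFT1-C291F, counts were 351 higher in mdm34Δ (604), 40 lower for VPS13-D716H in sam37Δ and 504 higher in clean YPD, and the genes higher in mmm1Δ had a median of -0.87 in the double mutant. At a mean FPKM of at least 20 the iron median in mmm1Δ was 2.10, counts were 248 higher in mdm34Δ, 75 lower in VPS13-D716H, 38 and 25 for VPS13-D716H in sam37Δ and 506 higher in clean YPD, and the median in the double mutant was -0.9985. With no filter the iron median in AFT1-C291F was 2.43, VPS13-D716H in sam37Δ had 111 and 103 genes, and the median in the double mutant was -0.546. Scaling by the median ratio changed clean YPD to 375 higher and 665 lower and import there to -0.050. Random lists not matched on expression set apart 13 lists in clean YPD, against 7.

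Other controls cross tables, so ratios were centred and hold batch differences. Against WT replicate 2, BPS had 496 genes higher and 765 lower and an iron median of 2.93 (2.23), and medians reversed for Yap1 to -0.20, ribosomal proteins to -1.65, ergosterol to -0.063 and zinc to -0.28. Against clean YPD, AFT1-C291F had an iron median of 2.48, with ribosomal proteins reversed to 0.88 and glycolysis to 0.49. On that control sam37Δ had 229 higher, 141 lower, an iron median of 1.32 (1.61) and ribosomal proteins at 0.0013, and VPS13-D716H sam37Δ an iron median of 1.20 (1.51).

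Without WT replicate 1, and so against WT replicate 2, mdm34Δ had 553 lower genes and an iron median of 2.66 (2.07), and import at 0.57, proteasome at -0.40, ribosome biogenesis at -0.058 and Gcn4 at 0.83 reversed. Without WT replicate 2, and so against WT replicate 1, AFT1-C291F had 1869 lower genes, an iron median of 1.65 and phosphate reversed to -0.21. VPS13-D716H then had 674 higher and 1621 lower genes, and iron at -0.73, respiration at 0.10 and drug resistance at -0.54 reversed. In sam37Δ there were 932 higher and 1780 lower genes, with iron at 0.99 and import reversed to -0.78. Clean YPD had 1814 lower genes and reversed iron at -0.89, import at -1.16 and Gcn4 at -0.61. Depth is unknown, so how far low counts limit genes near an FPKM of 0 cannot be given.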

Other observations

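All tests here but the one on gene length were chosen after their results were seen. Ribosomal protein genes were lower in both pairs of mmm1Δ and in sam37Δ. With a trend with abundance and length fitted on other genes removed, their median went from -1.66 to -0.10 in pair 1. There such a trend is a candidate explanation, and the parts of abundance and length were not separated. In pair 2 the median went only from -1.03 to -0.69, so the trend as fitted left a part unexplained. The fit left out ribosomal protein and glycolysis genes and may be poor at the highest abundance. Whether a trend is the whole cause in pair 2 is therefore open. In pair 1, 144 other long and abundant genes had a median of -0.75, which argues against short length as the only cause. These genes were less low than the ribosomal protein genes at -1.66, so an added effect of gene length stays open. Slower growth stays open as well. Ribosome biogenesis medians were 0.53 in pair 1 (-0.41 with WT replicate 2 as control) and -0.42 in pair 2. In sam37Δ the median of -1.70 became 0.0013 against clean YPD, as a library batch shared with those libraries would give. The iron regulon stayed at 1.32, which such a batch would not give. The change of control cannot tell such a batch from other differences between the control libraries. Ribosomal protein genes held 48.9% of the length-weighted FPKM in WT replicate 2 and 27.7% in clean YPD. The labels do not say which library was made with which kit, so batches could not be set against genotype directly.

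HUG1 and RNR3, targets of the checkpoint for DNA damage and stalled replication, were noticed after their values were seen. They rose in mmm1Δ by 4.63 and 2.83 and were at -5.58 and -2.75 for VPS13-D716H in mmm1Δ. In mdm34Δ they were higher by 4.14 and 2.60, and in sam37Δ by 2.95 and 1.23. Were this a response shared with iron limitation, BPS would raise them about as much, but their mean there was 0.35 against 3.73 in mmm1Δ, with HUG1 at 0.22 and RNR3, under the filter at 3.38 and 5.11, at 0.48. An earlier form of the test with RNR2 and RNR4 gave -0.89 with BPS over the 3 genes that passed the filter, and was replaced because RNR2 and RNR4 were not higher in both pairs of mmm1Δ.

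The hypoxic and cell wall mannoprotein genes had a median of 1.47 in mmm1Δ and 0.38 with BPS. With BPS, in 1 library over another, the list still stood apart, with 4 of 15 members at least 2-fold higher. Iron limitation of 4 hours in clean YPD thus raised these genes less than they were raised in mmm1Δ. Whether longer iron limitation would raise them as far was not tested. No other explanation was tested for them.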
